A study of Mus musculus with 6 samples.

How the data were processed

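Total RNA was extracted with TRI reagent, labelled with biotin as cRNA and hybridised to Affymetrix arrays, per the labels. The 6 samples are 3 of a mouse bone marrow mesenchymal stem cell population and 3 of a clone derived from it. The array type, its annotation and the genome build are not given in the sources used here.

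The deposited value table holds log2 expression per row, made by the authors with RMA and Partek per the submitters' processing notes, which give no version. RMA corrects background, quantile-normalizes the arrays and summarises probes, so a change in total RNA per cell is not visible and every value is relative to the rest of its array. The values lay between 3 and 15, which fits a log2 scale. RMA also compresses changes of dim genes, and signals near the lower quartile have no measured floor. The authors' deposited table lists, per the file headers, a p-value per row that is not adjusted for multiple testing and a signed linear fold of clone over population. Its log2 fold matched the difference of the group means of the value table to within 7.8e-05. A further 6 columns of per-array values in that table match no label by name and were not used.

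Groups were taken from the labels. Every one of the 35556 rows entered the test, since no table identified control rows. A linear model with moderated variances was fitted with limma 3.58.1 (lmFit and eBayes, defaults) in R 4.3.3, with 4 residual and 2.72 prior degrees of freedom, with two-sided p-values adjusted by Benjamini-Hochberg over all rows and a threshold of 0.05. All adjusted p-values of genes come from limma and all those of lists and chromosomes from its camera function, unless named otherwise. Fold changes are clone minus population on the log2 scale. Depth has no meaning for these arrays; the number of arrays limits the precision.

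Gene symbols came from the authors' deposited table: 25123 rows had one and 10433 had none, of which 1239 passed the gene test and stay unnamed. Symbols were updated through a RefSeq table of the assembly GRCm38.p6, where 18923 were current, 3890 matched as an older name, 22 through a gene identifier and 2288 not at all. Of the current symbols, 620 are also an older name of another gene, in 437 cases on another chromosome, and were kept as written. For the 1457 genes with several rows the row with the highest mean was used; rows of 5 genes passed in opposite directions. That assembly was used for names, chromosomes and gene order only, and no coordinates are given.

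A total of 42 gene lists (lineages, processes, other cell types, RNA quality) were fixed before the data were examined and tested by camera with a preset correlation of 0.01, with an estimated correlation as an alternative and fry beside it. Chromosomes were tested in the same way over 10642 genes above the median level, with medians relative to that of all of them. Neighbouring genes were also grouped in blocks of 20, and 1000 random sets matched on level were drawn per chromosome.

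Named genes followed a rule fixed before the data were examined. It took the 12 largest rises and the 12 largest falls among rows that passed, carried 1 symbol and did not overlap between groups, leaving out predicted, RIKEN, pseudogene, receptor-family, segment and small RNA genes. It added up to 4 members that passed the gene test for each list that passed and up to 2 for each other list, and 17 fixed genes whatever their result. Genes chosen after their values were seen are said to be so. In several lists the rule took members of 1 direction only although others passed the other way. In the cholesterol, p53, smooth muscle and stress lists those named as going the other way were added after their values were seen. For the antigen presentation, unfolded protein response, ribosomal protein, pluripotency and Polycomb lists, only members of 1 direction are given as examples. Some genes that the rule names are not reported here.

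Alternatives were the sample number as a block, quantile normalization again, centring of arrays, a filter on dim rows, variance trend with robust moderation, array weights, no moderation, an adjusted p under 0.01, a minimum fold of 1.5, rows averaged per gene, the authors' deposited p-values and leaving out each array. Other alternatives were chosen after seeing the data: rows with a symbol only, chromosomes centred, lists without chromosomes 3, 13 and 15, and chromosomes without genes changed at least 2-fold.

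The tests were tried on simulated arrays with the real row means and spreads, with every row drawn independently of the others. Of 50 rows changed per size, 2% were recovered at 0.25 log2 units, 50% at 0.5, 94% at 1 and 100% at 2, with 5 false calls among 128. The data had 8446 calls, which makes the adjusted threshold less strict there, so these shares do not describe the real test. A list and chromosome 13 lowered by 0.5, each in its own simulation, were both found with 0 other sets called. As the simulated rows were independent, this says nothing about sets called because their genes vary together. The first form of this test lowered both in the same arrays and called 2 other lists, cholesterol synthesis and histone genes, which have 3 of 23 and 20 of 22 members on chromosome 13; the simulations were then separated.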

Results

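Gene expression was measured on Affymetrix arrays in mouse mesenchymal stem cells, the adherent stromal cells of the bone marrow that can form bone, fat and cartilage. The series set a mixed bone marrow population beside a tertiary clone derived from that population. Each group had 3 arrays, made from independent cell samples grown to confluence. All 6 arrays held 35556 rows of log2 values, with array medians between 5.19 and 5.25 and lower quartiles between 4.54 and 4.58. Sizes and ranks of differences are not exact for genes whose mean level in either group lay below the array medians. Arrays of one group correlated across rows at r = 0.9946 to 0.9958, and arrays of different groups at 0.9749 to 0.9793; rows are not independent replicates. No 2 arrays of a group held exactly equal values in more than 5 rows, so none was an exact copy of another. Each array counted as 1 sample, as the labels give it. The labels do not say whether the samples came from separate animals, and p-values therefore measure the spread between these cultures of 1 population and 1 clone.

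The comparison asked how the expression profile of the population differed from that of a clone derived from it. Lpl, the lipoprotein lipase that releases fatty acids from circulating lipids, showed the largest rise. Its level went from 5.37 ± 0.01 in the population to 10.73 ± 0.12 in the clone (log2, mean ± SD, n = 3 each), a 41.0-fold difference. Xist, the non-coding RNA that coats the inactive X chromosome, showed the largest fall, from 11.03 ± 0.09 to 4.65 ± 0.07, or 82.9-fold. The clone level of Xist lay close to the lower quartiles of the clone arrays, 4.54 to 4.57. Among 35556 rows, 8446 (23.8%) changed at an adjusted p under 0.05 in limma's moderated test with Benjamini-Hochberg adjustment. Of these, 4553 were higher in the clone and 3893 lower, against 3818 and 4367 when arrays were centred on their medians, and 1012 differed at least 2-fold, 412 higher and 600 lower. Among 22300 named genes, 6486 changed, 3243 in each direction, and 311 were at least 2-fold higher against 547 at least 2-fold lower. All 3 arrays of one group lay above all 3 of the other in 37.2% of rows, where chance gives 10%.

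After Lpl, Angpt1, the angiopoietin that binds the receptor Tie2, rose most, by 4.94 ± 0.06 (log2 fold change ± SE), and Kitl, the ligand of the receptor Kit, by 4.80 ± 0.08. Gas6, a ligand of the TAM receptor kinases, rose by 4.62 ± 0.07. The imprinted genes Mest and H19 rose by 4.45 ± 0.11 and 4.39 ± 0.13; a further row for H19 rose by 2.88. Fmod, a small proteoglycan that binds collagen, rose by 4.33 and Hpgd, which degrades prostaglandins, by 4.16. Svep1 (3.94), Aldh1a7 (3.88), Sned1 (3.83) and Cebpa (3.78), a transcription factor of fat cell differentiation, completed the 12 largest rises, with adjusted p-values between 3.36e-07 and 1.47e-05. The population levels of Aldh1a7 (4.77), Angpt1 (4.78) and Mest (4.95) lay below the median of every array, which limits how exact these sizes are.

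Below Xist, Akr1c18, a steroid-reducing enzyme, had a log2 fold change of -4.60 ± 0.13, and Cth, which makes cysteine from cystathionine, one of -4.39 ± 0.07. The small heat shock protein gene Hspb8 (-4.24), the collagen cross-linking gene Loxl2 (-4.19), the smooth muscle actin gene Actg2 (-4.01) and the receptor gene Tnfrsf9 (-3.99) followed. Log2 fold changes were -3.81 for the lipoprotein receptor gene Vldlr, -3.70 for Ndrg1, -3.62 for the intermediate filament gene Nes and -3.57 for Enpp1, which makes the mineralisation inhibitor pyrophosphate. H2bc4 was listed at -3.68, but histone genes have near-identical copies and this value is uncertain. The clone levels of Akr1c18 (4.58) and Hspb8 (4.59) lay, as that of Xist did, close to the lower quartiles of the clone arrays, and those of Nes (4.86) and Cth (5.21) below the medians of the clone arrays, so the size and rank of these falls are not exact. Adjusted p-values of the 12 falls lay between 3.36e-07 and 6e-06, and the plot of the largest rises and falls gives the values per array.

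**Figure D1:**
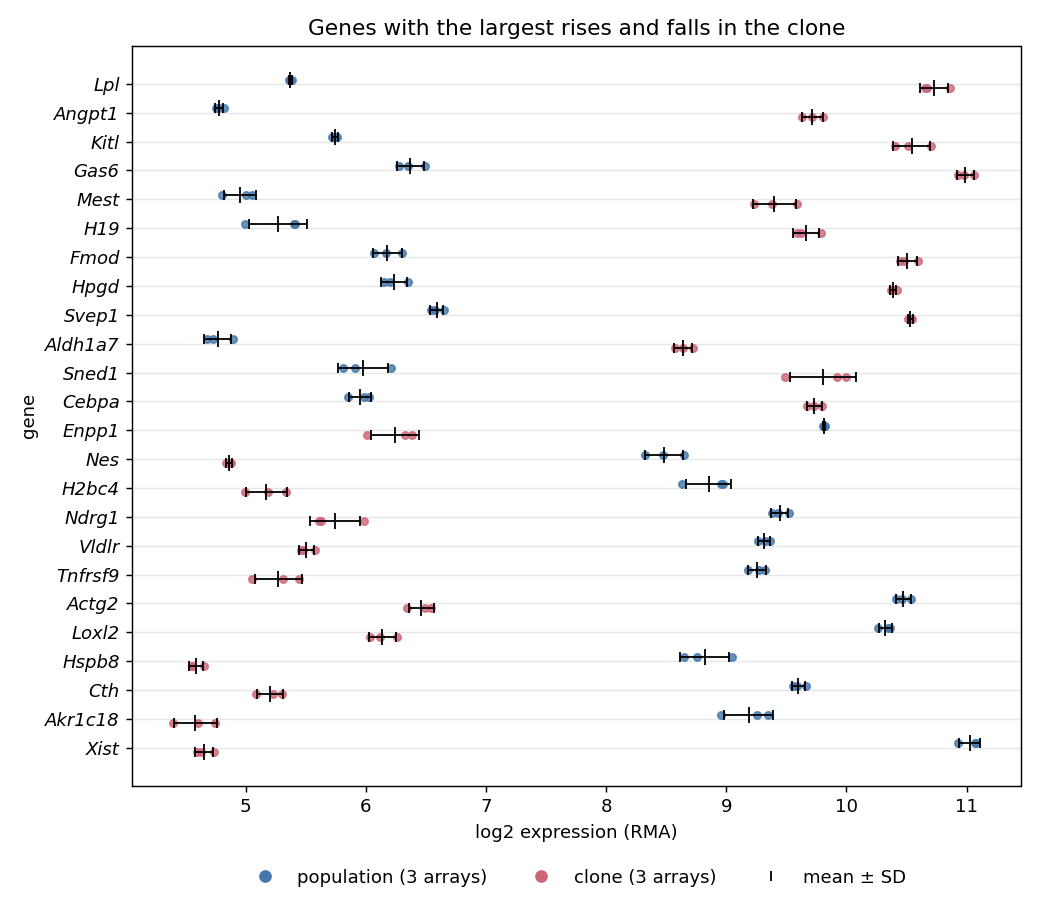
Log2 expression (x axis) of the 12 genes with the largest rises and the 12 with the largest falls in the clone (y axis), with 1 point per array for the 3 population arrays (blue) and the 3 clone arrays (red), and bars for the mean ± SD. The groups do not overlap for any of these genes, and Xist goes from 11.03 in the population to 4.65 in the clone.

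Surface and identity genes of mesenchymal stromal cells were mostly lower in the clone: of 22 measured, 12 fell and 4 rose (13 and 4 adjusted over the list alone). Nes (-3.62), the integrin gene Itga5 (-1.95), the leptin receptor gene Lepr (-1.83) and Thy1 (-1.82) fell most, though the clone levels of Nes (4.86) and Thy1 (4.61) lay near the low end and their sizes and ranks are not exact. The 4 that rose, named after their values were seen, were Twist2 (1.64), the platelet-derived growth factor receptor genes Pdgfra (1.43) and Pdgfrb (0.77), and Prrx1 (0.50). Ly6a, which encodes Sca-1, went from 10.70 ± 0.11 to 9.72 ± 0.16 and Cd44 from 8.27 ± 0.16 to 7.46 ± 0.10. Cd34 went from 10.14 to 9.02 ± 0.03. Eng, a further surface marker, did not pass the test (0.00 ± 0.06, adjusted p = 0.985), at levels of 4.89 and 4.88. The list passed the camera test (median log2 fold change -0.37, adjusted p = 0.00524), with an adjusted p = 0.315 with an estimated correlation. With only rows above the median level its median was -0.68 (adjusted p = 0.0139).

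Of 23 adipocyte genes 11 were higher in the clone and 3 lower (12 and 3 adjusted over the list alone), with a list median of 0.29 (camera adjusted p = 0.00161; adjusted p = 0.315 with an estimated correlation). Besides Lpl and Cebpa, the nuclear receptor gene Pparg rose by 1.78 ± 0.08 and Fabp4, a fatty acid carrier, by 1.64 ± 0.09. The 3 that fell, named after their values were seen, were Cebpd (-1.09, to a level of 4.98), Plin2 (-0.57) and Scd1 (-0.55). With only rows above the median level this list missed the threshold (adjusted p = 0.145). With each chromosome centred on its own median, a setting chosen after seeing the data, its median was 0.08 (adjusted p = 0.0268). Osteoblast genes moved both ways, 5 higher and 7 lower of 21 (6 and 7 adjusted over the list alone), and the list did not pass (adjusted p = 0.956); Alpl, the alkaline phosphatase of mineralising cells, rose by 3.42, Dlx5 by 2.35 and Runx2 by 0.58 ± 0.09. Of those that fell, Spp1, which encodes osteopontin, went from 13.46 to 11.50, Postn had a log2 fold change of -1.32 and Tnfrsf11b one of -0.74, all named after their values were seen. Of 20 chondrocyte genes 6 rose and 2 fell (adjusted p = 0.414), among them Sox9 at 1.96 ± 0.06 and Col11a1 at -3.00 ± 0.07.

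Contractile genes of smooth muscle fell in 10 of 16 cases and rose in 3 (median -0.50, camera adjusted p = 0.000664; adjusted p = 0.208 with an estimated correlation). Actg2, the calponin gene Cnn1 (-3.21), Tpm2 (-2.01) and Myl9 (-1.82) fell most, and Acta2 fell from 13.10 ± 0.03 to 12.60 ± 0.01; Mylk (0.50), Myocd (0.33) and Cnn2 (0.20) were the 3 that rose. Fibrillar collagen and matrix genes fell in 17 of 27 cases and rose in 5 (18 and 5 adjusted over the list alone; median -0.47, camera adjusted p = 0.000661; adjusted p = 0.337 with an estimated correlation). Loxl2 and Lum (-2.96 ± 0.16) fell, while Fmod and Col6a2 (2.20 ± 0.07) rose. Basement membrane genes split into 7 higher and 8 lower of 17 (adjusted p = 0.592), with Lama5 at -1.77, inexact at a clone level of 5.05, and Lama4 at -1.53; the type IV collagen genes Col4a6 (1.13, from a population level of 4.57), Col4a2 (0.96), Col4a1 (0.92) and Col4a5 (0.66), named after their values were seen, rose. Matrix proteases and their inhibitors gave 4 higher and 10 lower of 23 (5 and 11 adjusted over the list alone; adjusted p = 0.0605), including Adamts9 at 3.49, higher in all of its 6 rows, and Plau at -2.00.

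Glycolysis and hypoxia genes gave the lowest list p-value. Of 25 measured, 22 fell and none rose (24 and 0 adjusted over the list alone), with a median log2 fold change of -0.89, or 1.85-fold lower (camera adjusted p = 8.34e-17; adjusted p = 0.208 with an estimated correlation). Ndrg1, Pfkp (-2.69 ± 0.08), which encodes a phosphofructokinase, Egln3 (-2.12 ± 0.06), an oxygen-sensing hydroxylase, and Ero1a (-2.04 ± 0.09) fell most, the size for Egln3 being inexact at a clone level of 4.79. Unfolded protein response genes fell in 13 of 20 cases and rose in 1 (14 and 1 adjusted over the list alone; median -0.59, camera adjusted p = 1.42e-05; adjusted p = 0.208 with an estimated correlation). The members that fell most, Trib3 (-2.60), Chac1 (-1.40), Sesn2 (-1.08) and Atf4 (-0.80), belong to or lie downstream of the Atf4 branch, which amino acid shortage also engages. In the setting with chromosomes centred, chosen after seeing the data, the list median was -0.33 (adjusted p = 3.97e-05). Cholesterol synthesis genes fell in 14 of 23 cases and rose in 6 (median -0.36, camera adjusted p = 0.00704; adjusted p = 0.208 with an estimated correlation), among them Fdps (-0.97), Idi1 (-0.86) and Hmgcs1 (-0.83). Without the genes of chromosomes 3, 13 and 15, a setting chosen after seeing the data, that list had a median of -0.04 and an adjusted p of 0.507; with each chromosome centred instead it had -0.27 and 0.032. Mvk (0.56) and Dhcr7 (0.50) were the largest of the 6 that rose. Oxidative phosphorylation genes gave 10 higher and 5 lower of 30 (10 and 6 adjusted over the list alone; adjusted p = 0.623), with Ndufb9 at -0.65 and Cyc1 at -0.64, both on chromosome 15. The other 3 that fell lie on chromosome 13, and Sdhc (0.49) and Ndufs3 (0.40), named after their values were seen, rose most. Glutathione and NRF2 target genes gave 4 higher and 7 lower of 24 (adjusted p = 0.707), with Slc7a11, the cystine importer, at -2.73 and Gstt1 at 2.32.

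Antigen presentation genes rose in 12 of 17 cases and fell in 1 (median 0.62, camera adjusted p = 0.000107; adjusted p = 0.208 with an estimated correlation). The peptide transporter genes Tap1 and Tap2 rose by 1.57 ± 0.06 and 1.22 ± 0.07. The class I genes H2-D1 and H2-K1 were listed at 1.02 and 1.01, values that are uncertain because of near-identical relatives. Tap1, Tap2, H2-D1 and H2-K1 all lie on chromosome 17, whose genes were higher as a whole (relative median 0.20). The antigen presentation median was 0.42 (camera adjusted p = 0.00241) with each chromosome centred, a setting chosen after seeing the data. Interferon response genes rose in 8 of 29 cases and fell in 3 (11 and 3 adjusted over the list alone; median 0.18, camera adjusted p = 0.0466; adjusted p = 0.707 with an estimated correlation), and this list passed in 8 of 16 alternatives. Without clone array 1 its median was 0.10 (adjusted p = 0.121). Ifih1 (1.06) and Stat2 (0.95) rose while Cxcl10 (-0.76) and Gbp2 (-0.66) fell. Cytokines and chemokines gave 6 higher and 7 lower of 26 (adjusted p = 0.885), with Kitl up and Ptgs2 at -1.72. Complement genes gave 2 higher and 3 lower of 20 (adjusted p = 0.707), with Serping1 at -2.00.

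DNA replication genes rose in 14 of 26 cases and none fell (15 and 1 adjusted over the list alone; median 0.29, camera adjusted p = 0.000661; adjusted p = 0.315 with an estimated correlation). Gins1 (0.80), Rrm2 (0.77), Lig1 (0.67) and Mcm5 (0.60) rose most. Centring each chromosome on its own median, a setting chosen after seeing the data, gave a list median of 0.14 (adjusted p = 0.0195). Cell division genes split 5 and 5 of 25 (adjusted p = 0.934), with the proliferation marker Mki67 at 0.86 ± 0.12 and the cyclin gene Ccnb1 at -0.63. Ccnb1 lies on chromosome 13, whose genes were lower as a whole (relative median -0.61). Targets of p53 fell in 9 of 20 cases and rose in 4 (median -0.14, camera adjusted p = 0.0466; adjusted p = 0.315 with an estimated correlation), with Plk2 at -2.25, Gadd45a at -1.55 and the cell cycle inhibitor gene Cdkn1a at -1.37, inexact at a clone level of 4.62; the list passed in 9 of 16 alternatives, and its median was -0.23 (adjusted p = 0.0196) with each chromosome centred but -0.10 (adjusted p = 0.0909) without the genes of chromosomes 3, 13 and 15. Phlda3 (0.88) was the largest of its 4 rises. Trp53 itself did not pass the test (0.04 ± 0.05, adjusted p = 0.709). Cell cycle inhibitors and tumour suppressors gave 2 higher and 6 lower of 12 (adjusted p = 0.17), with Cdkn2b at -1.26 and Cdkn2a at -0.34 ± 0.08 (adjusted p = 0.0204, a call lost when any of population arrays 1 and 2 or clone arrays 1 and 2 was left out).

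Imprinted genes rose in 8 of 26 cases and fell in 3 (camera adjusted p = 0.0466; adjusted p = 0.315 with an estimated correlation), but the list median was 0.04. Mest and H19 rose, Igf2 rose 2.83-fold, and Slc38a4 (-2.91, to a level of 4.99 below the array medians) and Dcn (-1.89) fell. With each chromosome centred on its own median, a setting chosen after seeing the data, the median was -0.055 and the adjusted p 0.691, and the list passed in 12 of 16 alternatives. Its median was 0.86 with only rows above the median level, 0.004 with arrays centred, 0.021 without population array 2, 0.017 without clone array 3 and 0.05 without chromosomes 3, 13 and 15. The pathway lists did not pass. TGF-beta and BMP genes gave 13 higher and 7 lower of 37 (14 and 8 adjusted over the list alone; adjusted p = 0.0732), with Id1 5.50-fold and Id4 2.83-fold higher, the latter inexact at a population level of 4.90, and Skil at -1.32 and Tgfbr2 at -1.31. Wnt genes gave 13 and 10 of 39 (17 and 11 adjusted over the list alone; adjusted p = 0.252), with Rspo2 at 2.09, Sfrp2 at 2.03 and Ccn4 at -1.75. Notch genes gave 8 and 3 of 22 (adjusted p = 0.169), with Jag1 at 1.90, Lfng at 1.83 and Notch2 at -1.01. Skil, Tgfbr2, Ccn4 and Notch2 were named after their values were seen. Hox genes gave 5 and 5 of 39 (6 and 5 adjusted over the list alone; adjusted p = 0.745), with Hoxc13 at 2.38, from a population level of 4.59 at the low end, and Hoxc6 at -1.03. Pluripotency genes gave 1 and 5 of 23 (adjusted p = 0.485), with Myc at -1.14 and Tbx3 at -0.87, and DNA methylation and Polycomb genes 6 and 3 of 22 (adjusted p = 0.141), with Rnf2 at 0.82 and Bmi1 at 0.77.

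Markers of other cell types passed in none of their lists, all counts being higher and lower in that order. The pan-leukocyte gene Ptprc stood at 4.37 ± 0.06 in the population and 4.39 ± 0.07 in the clone, at the low end of the arrays. Myeloid markers gave 1 and 3 of 20 (adjusted p = 0.414), with Cd53 at -0.87 and Cd14 at -0.60, from levels of 5.35 and 5.37 to the low end. Lymphoid markers gave 0 and 0 of 16 (adjusted p = 0.715) and neutrophil and erythroid markers 0 and 0 of 15 (adjusted p = 0.608). Haematopoietic stem and progenitor markers gave 2 and 1 of 13 (adjusted p = 0.956), with Cd34 at -1.11 and Gata2 at 0.43. Endothelial markers gave 1 and 1 of 17 (0 and 0 adjusted over the list alone; adjusted p = 0.956), Egfl7 at 0.42 and Plvap at -0.25, calls that leaving out single arrays ended. Pericyte markers gave 4 and 1 of 10 (4 and 2 adjusted over the list alone; adjusted p = 0.592), including Mcam at -1.73 and Notch3 at 0.90. Epithelial markers gave 0 and 1 of 16 (adjusted p = 0.592; Krt19 at -0.87), skeletal muscle markers 2 and 1 of 17 (adjusted p = 0.956; Myod1 at 0.33 and Chrna1 at -0.28, the latter call ending without single arrays) and neural markers 0 and 5 of 17 (adjusted p = 0.121; Ncam1 at -1.08 and Stmn2 at -0.96). The 9 Y chromosome genes gave 0 and 0 (adjusted p = 0.956), and Ddx3y stood at 4.61 ± 0.19 and 4.59 ± 0.10.

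Among the lists that follow RNA and culture quality, ribosomal protein genes rose in 12 of 47 cases and fell in 1 (13 and 1 adjusted over the list alone; median 0.11, camera adjusted p = 0.0197; adjusted p = 0.707 with an estimated correlation). Rps28, Rpl26, Rps19 and Rpl6 rose by 0.40 to 0.47, and these genes have many near-identical copies; the list passed in 12 of 16 alternatives, with a median of 0.07 when arrays were centred on their medians. Heat shock and dissociation stress genes gave 3 higher and 8 lower of 17 (adjusted p = 0.0755), with Dusp1 at -1.57 and Ier3 at -1.22, and with Egr2 (0.61), Egr1 (0.49) and Fos (0.38) as the 3 that rose. Mitochondrially encoded genes gave 5 and 1 of 9 (7 and 1 adjusted over the list alone; adjusted p = 0.0755), with ND1 at 0.79, a call that leaving out single arrays ended, and ND6 at -0.90. Replication-dependent histone genes gave 4 and 0 of 22 (2 and 0 adjusted over the list alone; adjusted p = 0.0755), with H1f1 at 0.61 and H2ac4 at 0.51.

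**Figure D2:**
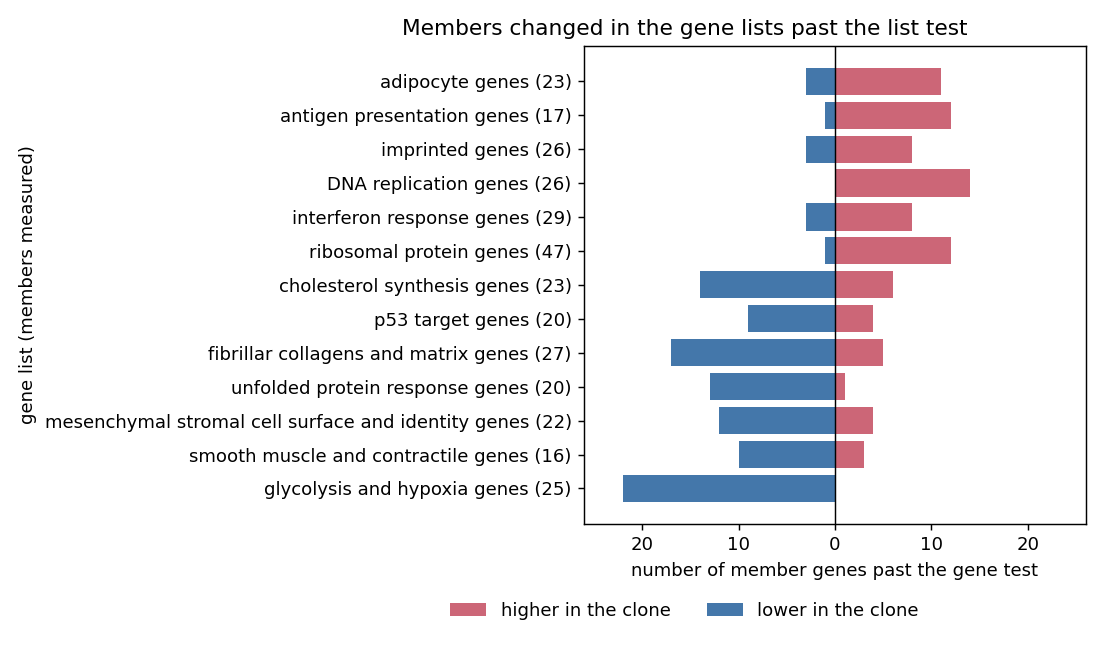
Number of member genes past the gene test (x axis) in each of the 13 gene lists past the camera test (y axis, members measured in brackets), with genes higher in the clone to the right (red) and lower to the left (blue). Glycolysis and hypoxia genes have 22 lower members of 25 and none higher, and DNA replication genes 14 higher of 26 and none lower.

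In all, 13 of the 42 lists passed the camera test with its preset correlation, 6 higher and 7 lower. None passed with a correlation estimated from the arrays, where the adjusted p-values of these 13 lay between 0.208 and 0.707. Lists whose estimated correlation lay below the preset lost their call too, so correlation between genes alone does not account for this. At an unadjusted p under 0.05 the preset test gave 18 lists, and fry, which asks whether the members of a list move one way on balance, gave 28. Median, mean and test differed in sign for the Y chromosome, cytokine, complement, pluripotency, haematopoietic progenitor and skeletal muscle lists, none of which passed.

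Whole chromosomes also differed between the clone and the population. Genes of chromosome 13 had a median log2 fold change of -0.61 relative to all 10642 genes above the median level, those of chromosome 15 one of -0.54 and those of chromosome 3 one of -0.46. On chromosome 13, 302 of 417 genes were lower in the clone and 20 higher; on 15 the counts were 306 and 23 of 433, and on 3 they were 328 and 44 of 536. These 3 chromosomes held 13.02% of the genes, 33.9% of the genes lower in the clone (936 of 2765) and 3.09% of those higher (87 of 2814). Many of the genes named above as lower lie on these chromosomes. Those on 13 include Akr1c18, H2bc4, Pfkp, Idi1, Hmgcs1, Ccnb1 and Plk2. On 15 lie, among others, Ndrg1, Myc, Slc38a4, Hoxc6, Atf4, Itga5, Ly6a, Tnfrsf11b, Ndufb9 and Cyc1. Cth, Nes, Col11a1, Slc7a11, Fdps, Cd53, Stmn2, Postn and Gbp2 are among those on 3. The falls of these single genes were not set against those of their chromosome. Other named genes there rose, among them Angpt1, Rspo2 and Hoxc13 on 15, Sfrp2 and Fabp4 on 3, and Id4 on 13. The mean shift of chromosome 13 over the clone arrays was -0.60 ± 0.01 (SD, n = 3). The population arrays varied with an SD of 0.008, around 0 by construction, since shifts were measured from their own mean. None of 1000 random gene sets of matched level lay as low as any of the 3. The same held for chromosomes 4, 9, 16 and 19, and none lay as high as chromosomes 2, 5, 7, 10, 11, 17 or 18. These draws therefore do not set the 3 apart. Blocks of 20 neighbouring genes lay below the median of all genes in 19 of 20 cases on chromosome 13, 20 of 21 on 15 and 25 of 26 on 3, but the first 7 blocks of chromosome 3 lay between -0.16 and 0.06 and its other 19 between -0.77 and -0.26.

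Chromosomes 19 (-0.24), 16 (-0.23), 4 (-0.23) and 9 (-0.12) were also lower, and 17 (0.20), 5 (0.19), 11 (0.18), 10 (0.17), 7 (0.14), 18 (0.13) and 2 (0.10) higher. Every block of chromosomes 4, 16 and 19 lay below the median of all genes, so a shift along the whole chromosome was not particular to 3, 13 and 15. The X chromosome (0.05, adjusted p = 0.251) did not pass, nor did chromosomes 1, 6, 8, 12 and 14 or the mitochondrial genes. In camera with the preset correlation 14 of 21 chromosomes passed, 7 higher and 7 lower. With an estimated correlation 9 passed (3, 4, 5, 11, 13, 15, 16, 17 and 19), at adjusted p-values of 0.0238 for 13 and 15 and 0.031 for 3. With dim genes included the medians were -0.13 on chromosome 13, -0.14 on 15 and -0.08 on 3. Those of the other chromosomes that had passed were then at most 0.06 in size, and chromosome 2 no longer passed. Chromosomes were assigned by gene name from the assembly GRCm38.p6, since the files name no build, and no DNA was measured.

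**Figure D3:**
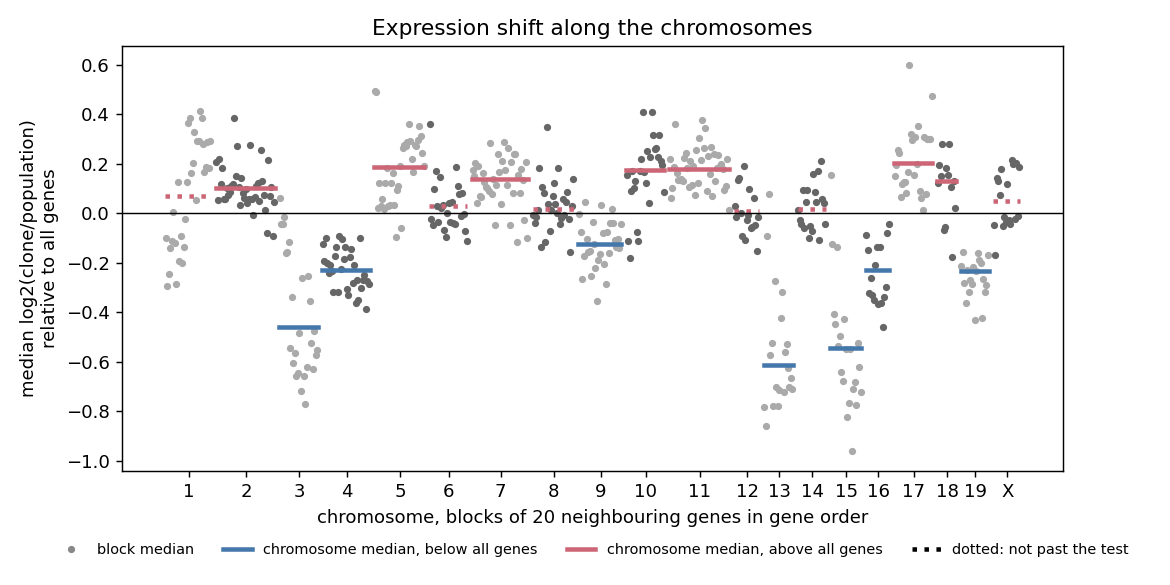
Median log2 ratio of clone over population in blocks of 20 neighbouring genes (points), relative to all genes (y axis), along the chromosomes in gene order (x axis), with lines for chromosome medians above (red) or below (blue) that of all genes, dotted where the chromosome did not pass the test. Chromosomes 3, 13 and 15 have medians of -0.46, -0.61 and -0.54.

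In the authors' deposited table an unadjusted p under 0.05 was listed for 10569 rows, against 11765 in limma's test. After adjustment here, 6252 rows of the authors' deposited table passed, 6001 of them among the 8446. The signed fold in the authors' deposited table was 40.96 for Lpl and -82.87 for Xist.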

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

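Settings without the genes of chromosomes 3, 13 and 15, with chromosomes centred, with symbol-bearing rows only or without genes changed at least 2-fold were chosen after seeing the data. The number of rows changed, 8446, was 5252 at an adjusted p under 0.01, with 2531 higher in the clone, and 1067 with a minimum fold of 1.5, with 383 higher and 684 lower; both tests ask for more by construction. It lay between 6630 and 7585 when single arrays were left out and was 6252 with the authors' deposited p-values. With arrays centred on their medians 46.6% of the changed rows were higher, against 53.9%. With an estimated correlation 0 lists passed, against 13, and 9 chromosomes, against 14. That setting replaces the preset 0.01 with a correlation estimated from 6 arrays, but this is not its only effect. Unfolded protein response and cholesterol synthesis genes had estimated correlations of -0.032 and -0.016, below the preset. They still went to a camera adjusted p of 0.208. The loss of the lists therefore cannot be put down to correlation between genes alone. Left-out arrays gave 10 to 15 lists and 14 to 14 chromosomes.

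Single values changed sign for 3 genes, none of which passed the test. Ptprc was -0.0165 with arrays centred. With single arrays left out Eng ranged from -0.0266 to 0.0329, Ptprc from -0.0153 to 0.0526 and Ddx3y from -0.103 to 0.0854. Under the alternatives 31 values of named genes lost their call and 1577 kept their side of the threshold and direction; the 31 belong to Cdkn2a, Egfl7, Plvap, Chrna1 and ND1. Of the values of the 13 lists 174 kept it and 34 lost it, 13 of them with the estimated correlation. Interferon genes lost it without population array 2 (adjusted p = 0.0581) or 3 (0.0702) and without clone array 1 (0.121) or 2 (0.0573), within a range of 0.00637 to 0.707. Targets of p53 lost it without population array 3 (0.052) or clone array 2 (0.0573), within 0.0196 to 0.315. Ribosomal genes lost it without population array 3 (0.0507) or clone array 2 (0.0887), within 0.00409 to 0.707, and imprinted genes without clone array 3 (0.0676), within 0.0291 to 0.691. For all of these the cause was not tested.

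With the sample number as a block 6669 rows changed, 6396 of them among the 8446; p53 targets (adjusted p = 0.0501), imprinted genes (0.0505) and the 5 genes above lost their call. Deviations of same-numbered samples correlated at -0.184, -0.139 and -0.035, and every sample correlated better with some other number. These values gave no sign of pairing by number. They cannot exclude it, since deviations were centred within each group and the correlations constrain one another. Chromosome medians were smaller with dim genes included; the cause was not tested, and signal over background was not analysed here.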

Other observations

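Tests of neighbouring blocks, upper quartiles, Y-linked and X-linked genes below were chosen only after the result was seen, as were the genes named in this and the next paragraph, the division of chromosomes into 2 parts and the list of amino acid response genes. Among the next 12 rises, the clone showed higher Hgf, the hepatocyte growth factor (log2 fold change 3.70 ± 0.11 SE), Il1rn, which blocks the interleukin 1 receptor (3.63 ± 0.12), the endothelin receptor gene Ednra (3.35), Fbn2 (3.23), Plxnd1 (3.22) and Stc1 (3.02). Cxcl12, a chemokine of the marrow stroma, rose from 11.38 ± 0.08 to 12.59 ± 0.04 (log2, SD, n = 3).

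Among the next 12 falls, Ccn2, a matricellular gene induced by TGF-beta and by tension, went from 11.20 ± 0.07 to 7.97 ± 0.11, and the lactate exporter gene Slc16a3 from 9.12 ± 0.04 to 5.56 ± 0.17. The X-linked genes Srpx (-3.28, to a level of 4.63 at the low end), Itm2a (-3.00) and Tspan7 (-2.88) fell while the X chromosome as a whole did not pass. Along chromosome 1, which did not pass as a whole and was parted where least squares fitted best, the first 14 blocks had a median of -0.13 and the other 17 one of 0.29. On chromosome 3 the first 7 blocks had a median of -0.04 and the other 19 one of -0.57, and on chromosome 15 the first 5 had one of -0.14 and the other 16 one of -0.66.

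Chromosomes 3, 13 and 15 were lower in the clone. Removing a trend on level and gene length left the highest of the 3 medians at -0.458, which argues against such a trend. Between 79.5% and 88.0% of their genes lay below the median of all genes, which argues against a few gene clusters; that at least 95% of blocks were lower nearly follows from this. Fewer copies of all or parts of these chromosomes in the clone may explain the pattern, as a hypothesis that no value here decides, since no DNA was measured. Their highest upper quartile was -0.03, below the median of 0.071 on the other chromosomes, but the shares of lower genes had fixed that outcome, and 7 of 26 blocks of chromosome 3 lay between -0.16 and 0.06.

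Xist was near the low end in the clone. Cells of a male source were argued against by Y-linked genes (median 0.003 over 4 genes), and reactivation of the silent X chromosome by the X-linked median of 0.05. Loss of the silent X chromosome may remain: 7 of 7 genes known to escape X inactivation were below 0, with a median of -0.183, and Eif2s3x (-0.84), Kdm5c (-0.46) and Pbdc1 (-0.63) passed, but 12.86% of random lists of matched level lay as low. It cannot be told apart from loss of Xist expression alone with 7 genes; 1 of them, Kdm6a, is also in the Polycomb list.

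Glycolysis and hypoxia genes were lower in the clone. With each gene set against its own chromosome the median was -0.968, which argues against chromosome copies as the cause. A hypoxia-inducible programme at another level in the 2 cultures may account for it: 14 other hypoxia-inducible genes had a median of -0.861, with 11 lower and 1 higher, Pgm1, a symbol that has also named another gene. Whether this came from the cells or from the state of the cultures at harvest is confounded with the groups and stays open.

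Cth, Slc7a11, Slc7a3 (-3.07, to a level of 5.21), Trib3 and Chac1, noticed among the falls, led to a further hypothesis, that an amino acid response programme may be at another level. In 20 other genes induced by amino acid shortage, not examined before that test, the median was -0.814 and 19 fell.

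The 6 arrays can be split in 10 ways into 3 against 3, too few for a share under 0.05. The real split gave 8446 changed rows and the highest other 0, with 1 split as large; 13 lists against 9, with 1 split as large; and 14 chromosomes against 15, with 4 splits as large, the real one included in each. By construction every other split still holds a part of the real difference, and the number of chromosomes past the test does not set the real split apart.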
